A study of Mus musculus with 20 samples.

How the data were processed

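Gene expression was measured in mouse regulatory T cells with Clariom S arrays, 1 array per sample and 20 arrays in all. Cells had been enriched with CD4 beads and sorted as CD4+CD25+ cells; their RNA was amplified and biotin-labelled before hybridisation. The deposited values were used as log2 gene-level signals, which the authors had made by RMA (background correction, quantile normalization and summarisation of probes) with Affymetrix Expression Console 1.1, per the labels. Whether both experiments were normalized together is not stated. Nothing was rescaled before the tests.

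The table held 28846 probe sets, of which 19572 carried 1 gene and 5222 were negative controls. A gene with several probe sets (55 genes) was represented by the probe set with the highest mean over all arrays, which left 19505 genes, and all of them were tested. A further 2634 probe sets carried no gene name in the annotation used here and were not assigned to genes. Foxp3, the transcription factor that defines regulatory T cells, is among the genes without a named probe set and was not analysed here. Each array was described by its median, its 99th percentile and the number of genes above the 95th percentile of its own negative controls. The number of arrays per group, 3 or 2, limits the precision.

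Groups were taken from the sample titles. The treatment field contradicts the titles for 6 arrays of the Rheb experiment, while the source names and the stated design match the titles. In each experiment, limma 3.58.1 in R 4.3.3 fitted 1 mean per group to its 4 groups, which share 1 estimate of spread per gene, and contrasts gave the knockout effect in each state, the effect of stimulation in each genotype and their interaction. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was below 0.05. The difference between the Rag and Rheb knockout effects was tested in 1 fit of all 8 groups, each effect being taken against the WT arrays of its own experiment. All tests are two-sided. Errors are standard errors (SE) of the fitted log2 change unless SD is named. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples.

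A set of 40 gene lists (934 genes written, 844 measured) covered signalling, metabolism, cell cycle, T cell programmes and marker genes of other cell types. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation between members estimated from the data. The fry test was run beside camera; it asks only whether members move in 1 direction on balance. The sets of genes responsive to stimulation were the 200 called genes with the largest rise, or fall, in WT arrays of the other experiment, or all of them where fewer were called. The groups, lists, tests, the rule for naming genes and all alternatives except 3 were chosen before the data were examined. The rule named the targeted genes, a few regulatory T cell and proliferation genes, the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between the groups, and up to 4 called members of each list that was called or had at least 3 called members. Genes with predicted or unnamed symbols were not eligible.

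The alternatives were a second quantile normalization, a filter removing the 40% of genes with the lowest mean signal, a trended and robust variance prior, only the 2 groups compared or all 20 arrays in the fit, the replicate number as a block, and each array left out in turn. The 3 alternatives added after seeing the data left out arrays numbered 2 of the Rag knockout, the Rag experiment arrays of lowest signal, and genes that followed macrophage markers within groups. Recovery of known changes was tested on simulated data with the same groups and spread. In 10 draws with 200 changed genes each, a 2-fold change was recovered for 96.4% of genes in a Rheb experiment contrast, 38.5% in a Rag experiment contrast and 6.87% in the Rag interaction. Of the genes called in these draws 4.51%, 8.33% and 9.9% had not been changed. A list of 30 genes shifted by 0.3 log2 was found at the preset correlation in 10 of 10 draws in a contrast of either experiment, and with an estimated correlation in 10 of 10 in the Rheb and 0 of 10 in the Rag experiment, where shifts of 0.8 were found in 10 of 10 draws for each knockout effect and each response. Genes vary independently in these simulations.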

Results

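Gene expression was measured in CD4+CD25+ regulatory T cells (Tregs, CD4 T cells that restrain immune responses) of C57BL/6 mice, without or after stimulation. In the Rheb experiment, 12 arrays held wild-type (WT) Tregs and Tregs lacking Rheb1 and Rheb2 (Rheb KO), 3 arrays for each genotype and state. In the Rag experiment, 8 arrays held WT Tregs and Tregs lacking RagA and RagB (Rag KO), 2 arrays for each genotype and state, with stimulation for 8 h. The stimulus, and its duration in the Rheb experiment, are not given in the sources used here. Rheb and the Rag proteins are small GTPases through which growth signals and amino acids switch on the kinase complex mTORC1. The comparisons ask which genes depend on each GTPase in resting and in stimulated Tregs, and whether the response to stimulation needs them.

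Array medians lay between 7.67 and 7.77 (log2 signal) in the Rheb experiment and between 7.18 and 7.55 in the Rag experiment. The 99th percentile of all genes lay between 11.99 and 12.07 in the Rheb experiment and between 11.3 and 12.1 in the Rag experiment. The wider spread in the Rag experiment is unexplained, since quantile normalization is part of RMA and would bring arrays close to each other. Between 2194 and 2914 genes per array exceeded the 95th percentile of the negative controls in the Rheb experiment, and between 2312 and 3548 in the Rag experiment. For 6 arrays of the Rheb experiment, the 3 of unstimulated KO and the 3 of stimulated WT, the treatment field names the opposite state to the title and source name. Groups followed the titles, under which arrays that this field would pool differed in 1828 genes in WT and 1901 genes in KO.

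The Rheb transcript was lower in every KO array than in every WT array of the same state. Its signal was 9.77 ± 0.40 (SD, n = 3) in unstimulated WT and 8.89 ± 0.13 in unstimulated KO, a fall of -0.88 ± 0.17 log2 (SE, adjusted p = 0.0413). In stimulated arrays it was 10.3 ± 0.17 in WT and 9.39 ± 0.08 in KO, -0.93 ± 0.17 (adjusted p = 0.0278). In the unstimulated state the call ended without WT array 1 (-0.85) or 3 (-0.70), and without KO array 1 (-0.84), 2 (-0.85) or 3 (-0.96). It also ended without stimulated WT array 2 or any 1 stimulated KO array (-0.88 each). In the stimulated state it ended without WT array 1 (-0.83), 2 (-1.002) or 3 (-0.96) and without KO array 1 (-0.92), 2 (-0.97) or 3 (-0.90). Rhebl1, which encodes Rheb2, changed by -0.38 ± 0.19 and -0.76 ± 0.19 (adjusted p = 0.522 and 0.119), from WT levels of 5.59 and 5.94 that lay below the median of the arrays. Rraga, which encodes RagA, fell by 2.43 ± 0.25 log2 in unstimulated Rag KO (adjusted p = 0.00266), from 9.26 ± 0.10 (SD, n = 2) to 6.83 ± 0.22. In stimulated Rag KO it changed by -2.18 ± 0.25 (adjusted p = 0.00448), from 9.52 ± 0.34 to 7.34 ± 0.23. The Rraga call ended in the unstimulated state without WT array 1 (-2.50) or 2 (-2.36) and in the stimulated state without KO array 1 (-2.02). Rragb, which encodes RagB, changed by -0.08 ± 0.30 and -0.22 ± 0.30 (adjusted p = 0.973 and 0.955). The deleted parts of the genes and the positions of the probes are not given in the sources used here. A probe outside the deleted part checks nothing, so Rragb and Rhebl1 leave the deletion of those genes unchecked. Rraga did not change detectably in Rheb KO (0.08 ± 0.13 and -0.13 ± 0.13, adjusted p = 0.904 and 0.875). Rheb was not called in Rag KO (-0.75 ± 0.29 and -0.04 ± 0.29, adjusted p = 0.681 and 0.994).

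**Figure D1:**
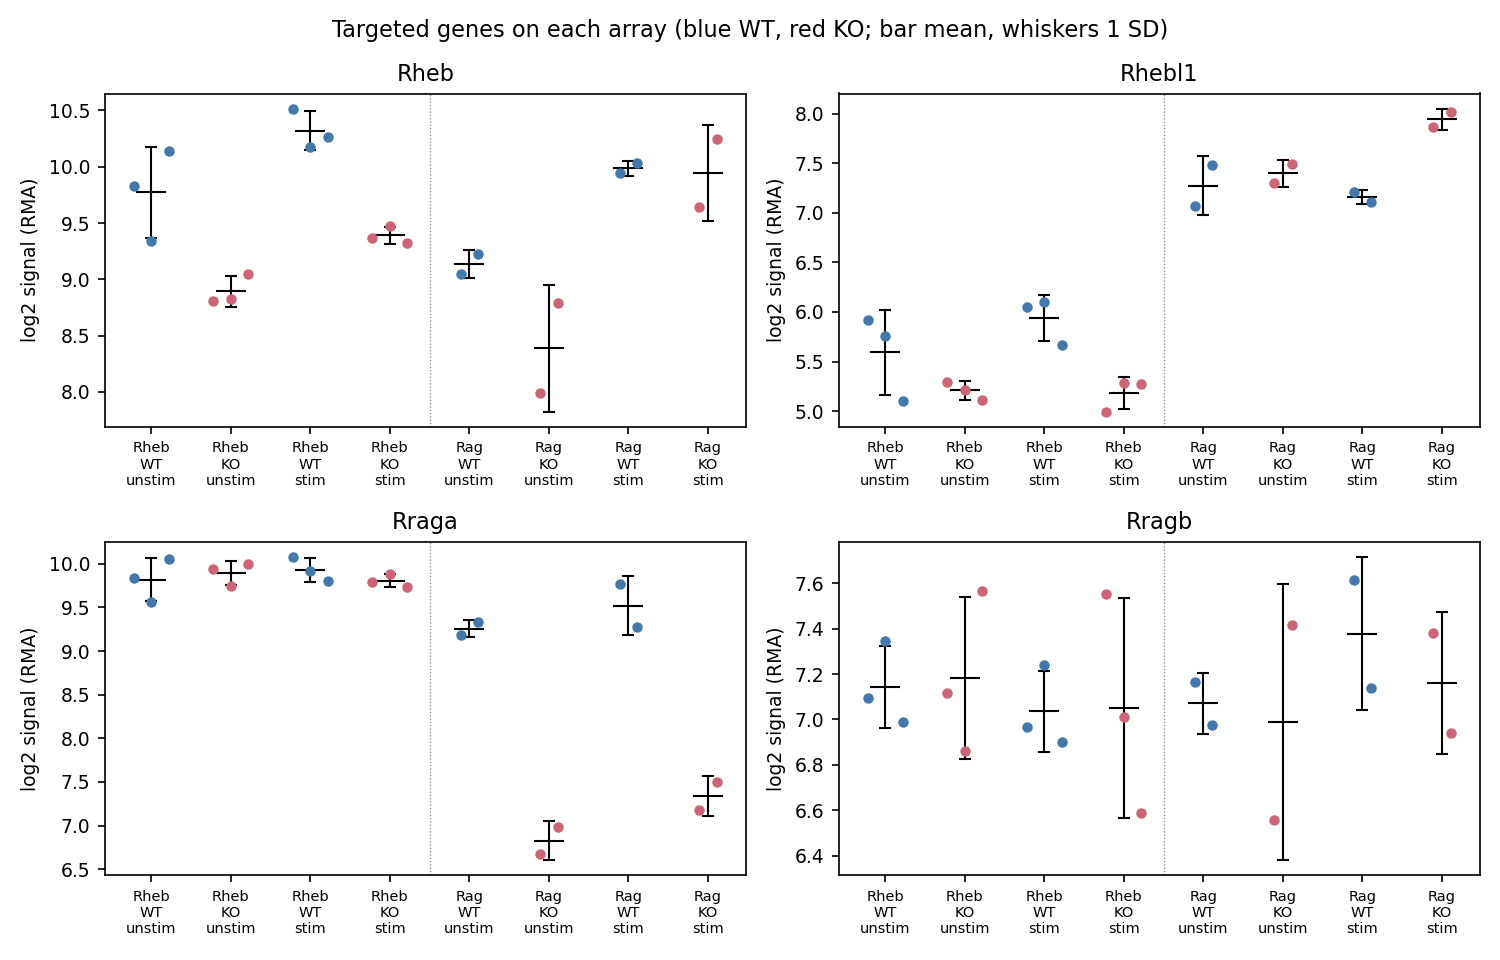
Log2 signal of Rheb, Rhebl1, Rraga and Rragb in each of the 20 arrays by group, with points for arrays and bars for the mean ± 1 SD. Rraga averaged 6.83 and 7.34 in the Rag KO groups against 9.26 and 9.52 in their WT groups, and Rheb averaged 8.89 and 9.39 in the Rheb KO groups against 9.77 and 10.3.

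In unstimulated Rheb KO arrays, cell cycle and sterol synthesis genes, part of the Treg signature and a few cytokine genes were lower. Il10 and Il4, which encode interleukins secreted by T cells, were lower by -1.36 ± 0.21 and -1.31 ± 0.16 log2 (SE, n = 3 arrays per group; adjusted p = 0.0113 and 0.00485). The mitotic kinesin Kif15 (-1.33 ± 0.25), the purine-degrading enzyme Xdh (-1.26 ± 0.22), Ccdc152 (-1.26 ± 0.19) and the secreted lubricant Prg4 (-1.19 ± 0.18) also fell. The largest rises were those of the steroid-converting enzyme Akr1c18 (2.04 ± 0.28, adjusted p = 0.00682), the adhesion molecule Dscam (1.55 ± 0.17) and Aqp11 (1.54 ± 0.29). The Notch ligand Jag1 (1.31 ± 0.17), the semaphorin Sema6d (1.28 ± 0.13) and Rasgrp4 (1.23 ± 0.18) rose as well. In all, 99 of 19505 genes were called, 44 higher and 55 lower, and 1986 had an unadjusted p under 0.05. In their dimmer group Akr1c18, Aqp11, Il4, Ccdc152 and Rsad2 lay below the 25th percentile of each array compared, so the sizes of their changes are uncertain. Il2ra, Ctla4, Myc and Mki67 were not called (-0.29, -0.37, 0.05 and -0.43). The Il2ra means, 7.34 in WT and 7.05 in KO, lay below every array median of the experiment, which limits what this gene can show.

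Of 17 core Treg genes, 4 fell, 1 rose and 12 were not called (median -0.29, camera, adjusted p = 4.4e-09). Adjusted over the list alone, 8 fell and 1 rose. Those that fell were led by the cytokine signalling inhibitor Socs2 (-0.91 ± 0.13), Nt5e (-0.71 ± 0.10) and Entpd1 (-0.70 ± 0.14), while Penk rose (0.69 ± 0.13). Nt5e and Entpd1 encode CD73 and CD39, ectoenzymes that make adenosine. Among 38 genes of mitosis, Cdk1 fell (-0.86 ± 0.11) and 37 were not called, with 8 lower when adjusted over the list alone (median -0.28, adjusted p = 2.7e-09). None of 38 genes of DNA replication and the G1/S transition was called (median -0.18, adjusted p = 3.1e-08), and 4 were lower when adjusted over the list alone. Of 20 sterol synthesis genes 19 lay below 0 and none was called (median -0.28, adjusted p = 1.5e-08), with 2 lower when adjusted over the list alone. The integrin genes Itgb1 (-0.57) and Itga4 (-0.54) fell among 22 migration genes of which 20 were not called, 3 falling and 1 rising when adjusted over the list alone (adjusted p = 0.0162; adjusted p = 0.285 with an estimated correlation). The migration list was not called without WT array 3 (-0.0939) or KO array 1 (-0.0868) or after a second quantile normalization (-0.0324). Oxidative phosphorylation genes shifted by a median of -0.10 with none of 43 called (adjusted p = 5.8e-06; adjusted p = 0.271 with an estimated correlation). Beside Il10 and Il4, 22 of 24 cytokine genes were not called, 3 fell when adjusted over the list alone, and the list was not called (median -0.02, adjusted p = 0.0608). The interferon list was not called (adjusted p = 0.175), with Rsad2 higher (0.76) and Gbp2 and Gbp3 lower (-0.69 and -0.58). Macrophage marker genes were higher in the same arrays, all 12 above 0 (median 0.44, adjusted p = 6.7e-08). C1qa (1.14 ± 0.19) and Ms4a7 (0.84 ± 0.16) were called, and 8 were higher when adjusted over the list alone. Among 12 dendritic cell genes the MHC class II genes H2-Eb1 (0.83) and H2-Ab1 (0.73) were called, 3 were higher when adjusted over the list alone, and the list shifted by 0.27 (adjusted p = 0.00016). Natural killer (NK) cell genes were higher too, 8 of 10 above 0, with Fcgr3 called and 4 when adjusted over the list alone (median 0.26, adjusted p = 0.0020; adjusted p = 0.101 with an estimated correlation). With these rises in the same arrays, the fall of core Treg genes is not shown to be a change within Tregs. Of 40 lists, 16 were called. These 6 held with an estimated correlation: core Treg, G1/S, mitosis, sterol, macrophage and dendritic, with adjusted p from 0.0203 to 0.0417, and fry called 7. Without 1 array the number of genes called was 54 (WT array 1), 39 (WT array 3), 41 and 40 (KO arrays 1 and 2), or 52, 61 and 60 (stimulated KO arrays 1, 2 and 3). Akr1c18, Dscam, Jag1, Sema6d, Rasgrp4, Il4, Socs2, Nt5e and Cdk1, 9 of 28 named genes called, were called whichever array was left out.

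**Figure D2:**
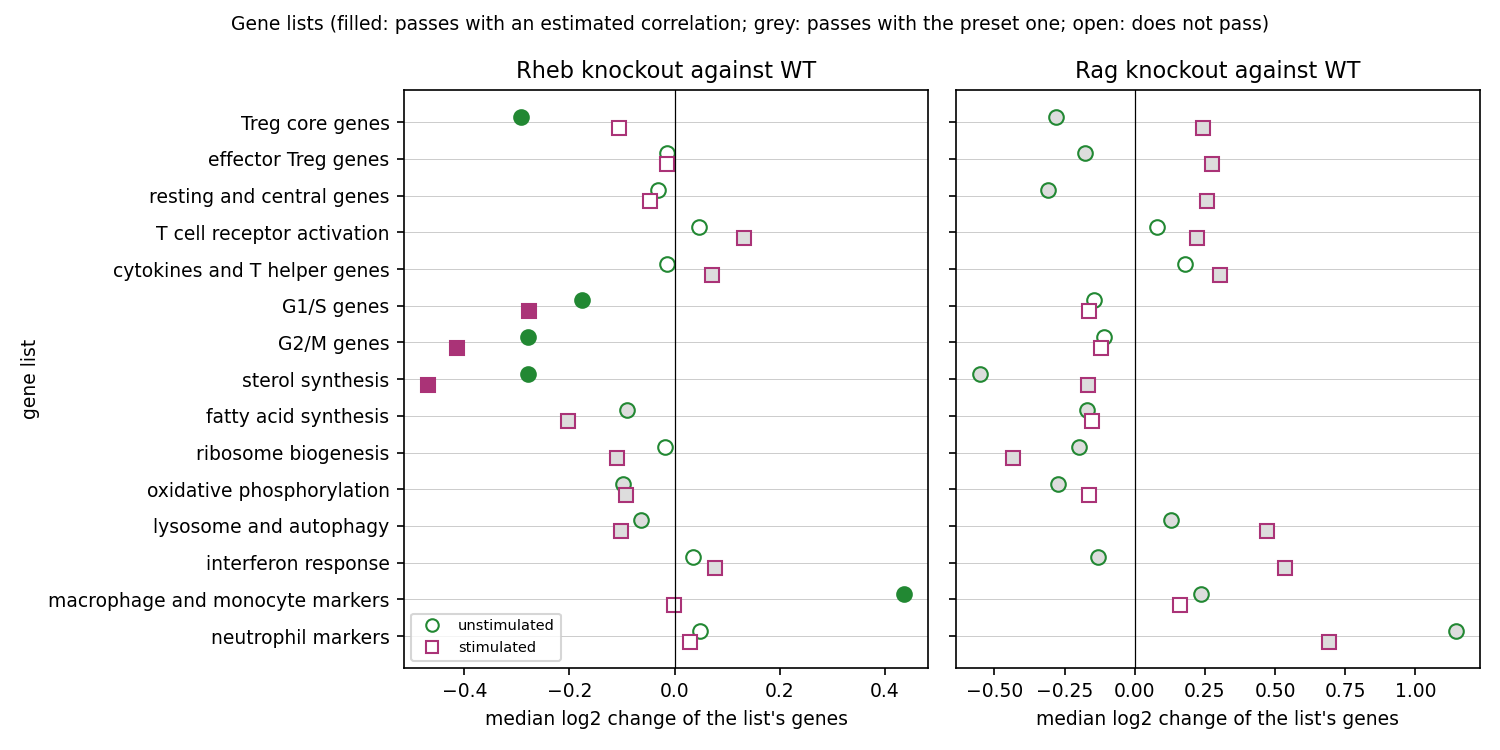
Median log2 change of the members of each gene list (x axis) in the Rheb KO (left) and Rag KO (right), unstimulated (circles) and stimulated (squares), filled in colour where the list passed with an estimated correlation, grey where it passed only with the preset correlation and open where it did not pass. The sterol list sits at -0.28 and -0.47 and the mitosis list at -0.28 and -0.41 in the Rheb KO.

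In stimulated Rheb KO arrays sterol synthesis and cell cycle genes were lower, and the signal of the cytokine and chemokine genes Il3, Csf2, Cxcl9 and Xcl1 was higher. The haematopoietic growth factor gene Il3 was higher by 2.94 ± 0.35 log2 (SE, n = 3 arrays per group; adjusted p = 0.0034), at 7.90 ± 0.93 (SD) against 4.96 ± 0.39 in WT. The WT level lay below the median of the negative controls and, like those of Ermn, Cxcl9 and Dscam, below the 25th percentile of each array compared, so the sizes of these rises are uncertain. Other rises were those of Ermn (1.78 ± 0.17) and the chemokine genes Cxcl9 (1.502 ± 0.24) and Xcl1 (1.102 ± 0.19). Dscam (1.43 ± 0.17) and Jag1 (1.15 ± 0.17) rose as well and had also been higher without stimulation. Fam110c (-1.73 ± 0.14, adjusted p = 0.000208), Xdh (-1.70 ± 0.22), Pdzk1ip1 (-1.28 ± 0.19), the chemokine gene Ccl20 (-1.23 ± 0.12) and Castor2, a relative of an arginine sensor upstream of mTORC1 (-1.23 ± 0.14), fell most. Of 19505 genes 106 were called, 40 higher and 66 lower, and 1804 had an unadjusted p under 0.05. Il2ra, Ctla4, Myc and Mki67 were not called (-0.10, -0.15, 0.22 and -0.71).

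Of 20 sterol synthesis genes, Sqle (-0.87 ± 0.17), Nsdhl (-0.79 ± 0.11) and Fdps (-0.61 ± 0.11) fell and 17 were not called (median -0.47, adjusted p = 6.3e-18). Adjusted over the list alone, 16 were lower. Of 38 mitosis genes 6 fell, led by Ube2c (-1.05 ± 0.18), Cdk1 (-0.98 ± 0.11) and the mitotic kinase genes Plk1 (-0.94) and Aurkb (-0.86) (median -0.41, adjusted p = 3.9e-18). Adjusted over the list alone, 18 were lower. Of 38 G1/S genes the transcription factor gene E2f2 (-1.18 ± 0.19) and the cyclin gene Ccne2 (-0.90 ± 0.15) fell, and 4 were lower when adjusted over the list alone (median -0.28, adjusted p = 3.8e-12). Fatty acid synthesis genes shifted by -0.20 with none of 17 called and 2 lower when adjusted over the list alone (adjusted p = 0.00062; adjusted p = 0.0849 with an estimated correlation). Among 35 genes induced by the T cell receptor, 28 lay above 0 and Nr4a2 (0.74 ± 0.12), Nr4a3 (0.58 ± 0.11) and Cd69 (0.45 ± 0.08) rose. When adjusted over the list alone 6 rose (median 0.13, adjusted p = 5.4e-08; adjusted p = 0.104 with an estimated correlation). Il3, Xcl1 and Csf2 (0.73 ± 0.12) rose among 24 cytokine genes, 5 rising and 3 falling when adjusted over the list alone (adjusted p = 0.0066; adjusted p = 0.248 with an estimated correlation). In the migration list, which was not called (adjusted p = 0.902), the chemokine receptor gene Ccr6 rose (0.75) while Ccr4 (-0.75) and Itga4 (-0.61) fell. In that list 5 rose and 5 fell when adjusted over the list alone. The core Treg list was not called after stimulation (median -0.11, adjusted p = 0.459), nor was the macrophage list. NK cell genes were again higher, 8 of 10 above 0 with none called by either adjustment (median 0.19, adjusted p = 0.0035; adjusted p = 0.104 with an estimated correlation). Of 12 dendritic genes H2-Eb1 rose (0.78), 1 when adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.104 with an estimated correlation), and the list was not called without WT array 1 (0.11) or 2 (0.15). The mean of the conventional CD4 T cell list was higher too (0.16 ± 0.0529, SE), though 6 of its 7 genes exceeded the median of every unstimulated WT array. With these rises, those of Il3, Csf2, Cxcl9 and Xcl1 are not shown to be changes within Tregs. Of 40 lists 20 were called, and the sterol, mitosis and G1/S lists held with an estimated correlation (adjusted p = 0.00826, 0.012 and 0.00933), while fry called 8. Without 1 array the number of genes called was 25, 34 and 37 (WT arrays 1, 2 and 3) or 28, 25 and 44 (KO arrays 1, 2 and 3). Il3, Ermn, Dscam, Fam110c, Xdh, Ccl20, Castor2 and Cdk1, 8 of 29 named genes called, were called whichever array was left out.

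In stimulated against unstimulated arrays of the Rheb experiment, genes of resting Tregs, of cell dissociation and of macrophages and dendritic cells were lower in both genotypes. The stimulus and its duration are not given, so its effect cannot be told apart from one of time since the sort. The falls of macrophage and dendritic genes are not shown to be changes within Tregs. In WT Tregs the zinc finger gene Zfp948 (2.71 ± 0.18 log2, SE, n = 3 arrays per group), Il4 (2.38 ± 0.16) and Mpzl1 (2.20 ± 0.25) rose most. Ramp3 (1.96 ± 0.18), the interferon-inducible GTPase gene Iigp1 (1.94 ± 0.13) and Fam110c (1.83 ± 0.14) followed. The immediate early genes Fosb (-3.55 ± 0.11, adjusted p = 1.7e-09) and Fos (-2.72 ± 0.14), the lysosomal galactosidase gene Gla (-3.12 ± 0.32), Ifit1bl1 (-2.39 ± 0.18), Aif1 (-2.38 ± 0.17) and Dtx1 (-2.31 ± 0.15) fell most. In Rheb KO, Il3 (3.47 ± 0.35, from 4.43, below the median of the negative controls), Il4 (3.20 ± 0.16), Zfp948 (3.11 ± 0.18), Ccl1 (2.94 ± 0.32), Gbp2 (2.88 ± 0.14) and Iigp1 (2.48 ± 0.13) rose most. Fosb (-2.96 ± 0.11), Aif1 (-2.74 ± 0.17), Gla (-2.43 ± 0.32), Fos (-2.41 ± 0.14), Dtx1 (-2.33 ± 0.15) and C1qa (-2.30 ± 0.19) fell most. Below the 25th percentile of each array compared, in their dimmer group, were Gla, Aif1 and Oas2 in WT and Il3, Il4 and Aif1 in KO, which leaves the sizes of their changes uncertain. In stimulated KO, C1qa (mean 6.42) and the macrophage gene Csf1r (at most 6.78) lay below the negative control median of each KO array, so their falls are of uncertain size too. Il2ra was called in KO (0.76 ± 0.18, adjusted p = 0.016) and not in WT (0.56 ± 0.18, adjusted p = 0.0723). The difference itself was not called (0.19 ± 0.26, adjusted p = 0.966). Unstimulated Il2ra means (7.34 in WT, 7.05 in KO) lay below every array median, so the sizes of its changes are uncertain. Genes called numbered 1828 in WT (875 higher, 953 lower) and 1901 in KO (888 higher, 1013 lower), 1126 of them in both genotypes, of which 3 went opposite ways.

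Of 24 genes of resting and central Tregs 14 fell in each genotype, led in WT by Id3 (-2.19 ± 0.25), Pik3ip1 (-1.14 ± 0.20) and Il6ra (-1.14 ± 0.09). Adjusted over the list alone, 17 fell in WT, and in KO 16 fell and 1 rose (median -0.58 and -0.51, adjusted p = 1.5e-15 and 2.6e-11). Of 19 genes that cell dissociation induces, such as Fosb, Fos, Zfp36 and Dusp1, 15 fell in WT and 16 in KO, 15 and 17 when adjusted over the list alone (median -0.87 in each, adjusted p = 1.2e-23 and 1.1e-21). In the same comparisons 8 of 12 macrophage genes fell in each genotype, Csf1r by -1.37 ± 0.19 in WT and -2.16 ± 0.19 in KO. With p adjusted over the list alone, 8 and 11 were lower (median -0.54 and -0.78, adjusted p = 1.6e-06 and 1.3e-11). Of 12 dendritic genes 5 fell in each, H2-Eb1 by -1.50 and -1.55, and 6 and 5 when adjusted over the list alone (median -0.43 and -0.39, adjusted p = 0.00045 and 7.3e-05). These 4 lists held with an estimated correlation in both genotypes, with adjusted p from 0.00642 to 0.0332, and fry called 24 lists in WT and 21 in KO. Of 33 effector Treg genes 10 rose and 4 fell in WT, including the inhibitory receptor gene Pdcd1 (1.69 ± 0.16), Itgb8 (1.25 ± 0.15), Tnfrsf9 (1.22 ± 0.13) and the granzyme gene Gzmb (0.97 ± 0.21). When adjusted over the list alone 12 rose and 5 fell (adjusted p = 0.0098; adjusted p = 0.386 with an estimated correlation), and the list was not called without unstimulated WT array 2 (0.19). Ribosome biogenesis genes rose in WT, 7 of 42 and 13 when adjusted over the list alone, with Noc4l (0.82) and Nop2 (0.62) first (adjusted p = 5e-07; adjusted p = 0.156 with an estimated correlation). Hmgcs1 (1.03), Msmo1 (1.01) and Fdps (0.99) were among 5 of 20 sterol genes that rose in WT, while 1 fell. Adjusted over the list alone, 10 rose and 1 fell (adjusted p = 0.0016; adjusted p = 0.178 with an estimated correlation). Interferon genes were split in WT, with Gbp2 higher (1.80 ± 0.14) and Cmpk2 (-1.47), Oas2 (-1.40) and Irf7 (-1.29) lower. Of 36 genes 5 rose and 13 fell, or 6 and 18 when adjusted over the list alone (adjusted p = 7.3e-05; adjusted p = 0.337 with an estimated correlation). In KO, 9 of 17 core Treg genes rose and 2 fell, led by Socs2 (1.37), Gpr83 (1.11), Nt5e (0.97) and Lrrc32 (0.88). The same numbers rose and fell when adjusted over the list alone (adjusted p = 0.00018; adjusted p = 0.169 with an estimated correlation). The mitosis, ribosomal protein, sterol and nucleotide lists were called in WT and not in KO. The core Treg, cytokine, translation initiation, p53 and NK lists were called in KO and not in WT, and of all these the core Treg, cytokine and sterol lists were called for the difference between the genotypes. None of these calls held with an estimated correlation (adjusted p from 0.178 to 0.386 in WT, from 0.169 to 0.429 in KO and from 0.115 to 0.56 for the difference). The ribosomal protein, translation initiation, p53 and NK calls also ended with 1 or another array left out (highest adjusted p = 0.0549, 0.119, 0.101 and 0.152), the first 3 also after a second quantile normalization.

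Whether loss of Rheb altered the response to stimulation was asked by the interaction of genotype and state. No gene was called by limma, 1207 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.0704, for Pik3ap1. Across genes, which are not independent replicates, the responses in WT and KO correlated with r = 0.72. The response of the core Treg list lay higher in KO than in WT by camera (median 0.19, 16 of 17 above 0, none called and 3 higher when adjusted over the list alone; adjusted p = 1.3e-06; adjusted p = 0.115 with an estimated correlation). That of the macrophage list lay lower in KO (median -0.31, all 12 below 0, none called and 5 lower when adjusted over the list alone; adjusted p = 3.6e-05; adjusted p = 0.115 with an estimated correlation). T cell receptor genes (median 0.16, 25 of 35 above 0, 5 higher and 1 lower when adjusted over the list alone; adjusted p = 6.7e-05; adjusted p = 0.496 with an estimated correlation) and cytokine genes (median 0.09, 18 of 24 above 0, 6 higher when adjusted over the list alone; adjusted p = 2.5e-05; adjusted p = 0.262 with an estimated correlation) shifted higher, with none called. These 4 lists were called whichever array was left out. In unstimulated arrays the core Treg list had been lower in KO (median -0.29). The macrophage list mean had been higher there (0.45 ± 0.0694, SE), against -0.0138 ± 0.0694 in stimulated KO. Both lists thus differed already without stimulation, and their interactions are not shown to be a changed response of Tregs. The sterol list shifted by -0.16 (1 lower when adjusted over the list alone; adjusted p = 0.0289; adjusted p = 0.56 with an estimated correlation). It was not called without unstimulated WT array 2 (-0.12), unstimulated KO array 3 (-0.17), stimulated WT arrays 1 (-0.18) and 2 (-0.16) or stimulated KO array 2 (-0.15). The list of Foxo targets shifted by 0.14 (none called by either adjustment; adjusted p = 0.037; adjusted p = 0.56 with an estimated correlation). It was not called without unstimulated WT arrays 2 and 3 (0.16 each), unstimulated KO array 1 (0.12), stimulated WT arrays 1 and 3 (0.12 each) or stimulated KO arrays 1 (0.0858) and 2 (0.12), nor after a second quantile normalization (0.15). Of 40 lists 6 were called for the interaction, none held with an estimated correlation and fry called none (smallest adjusted p = 0.0772).

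In unstimulated Tregs 22 genes, Rraga included, were called for loss of Rag, each changed at least 2-fold. Smaller changes would mostly be missed with 2 arrays per group, since simulated 1.41-fold changes were recovered for 0.896% of genes in this experiment and 2-fold changes for 38.5%. The prostaglandin D synthase gene Hpgds was higher by 2.83 ± 0.41 log2 (SE, n = 2 arrays per group; adjusted p = 0.023) and Eps8l1 by 2.57 ± 0.26 (adjusted p = 0.00266), the latter from a WT level below the 25th percentile of each array compared. The integrin gene Itga9 (2.40 ± 0.27), the collagen gene Col27a1 (2.27 ± 0.27), Trpm1 (2.13 ± 0.31) and the gut-homing receptor gene Ccr9 (1.87 ± 0.32) were higher too. Prg4 (-1.81 ± 0.25), Nt5e (-1.80 ± 0.24), Rnf32 (-1.78 ± 0.27), the fatty acid elongase gene Elovl5 (-1.72 ± 0.28) and the T cell receptor adaptor gene Trat1 (-1.63 ± 0.28) fell. Rnf32 averaged 5.83 in KO, below the negative control median of each unstimulated array (6.11 to 6.62), so the size of its fall is uncertain. Of the 22 genes called 10 were higher and 12 lower, and 1300 had an unadjusted p under 0.05; after a second quantile normalization 43 were called, 26 higher and 17 lower. Il2ra, Ctla4, Myc and Mki67 were not called (0.12, -0.69, 0.18 and -0.41).

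Among lists, sterol synthesis genes shifted lower, with none of 20 called and 4 when adjusted over the list alone (median -0.55, adjusted p = 1.4e-06). So did tRNA synthetase genes, with none of 20 called by either adjustment (median -0.34, adjusted p = 5.3e-05). Oxidative phosphorylation genes moved the same way, with none of 43 called by either adjustment (median -0.27, adjusted p = 1.4e-05). Of 17 core Treg genes Nt5e fell, and 5 fell and 1 rose when adjusted over the list alone (median -0.28, adjusted p = 0.0050; 0.0923 and not called without WT array 1, -0.0802 and not called after a second quantile normalization). Of 24 resting genes Dapl1 fell (-1.40 ± 0.22), 1 when adjusted over the list alone (median -0.31, adjusted p = 0.00024; -0.14 and not called after a second quantile normalization). Neutrophil marker genes were higher, all 10 above 0 and none called by either adjustment (median 1.14, adjusted p = 0.0004; 0.23 and not called without KO array 2). NK genes (8 of 10 above 0, none called and 1 higher when adjusted over the list alone; median 0.39, adjusted p = 0.0038) and macrophage genes (10 of 12 above 0, none called by either adjustment; median 0.23, adjusted p = 0.0379) were higher with them. Neither list was called without WT array 1 (0.59 and 0.42) or KO array 2 (0.10 and 0.17) or after a second quantile normalization (0.30 and 0.14), nor the macrophage list without WT array 2 (0.0749). The dendritic list was called higher as well, with Ccr9 alone of 12 genes called and 4 when adjusted over the list alone (median 0.34, adjusted p = 1.9e-05). Of 40 lists 23 were called. None held with an estimated correlation (adjusted p = 0.763 with an estimated correlation for each list named). Nor did fry call a list (smallest adjusted p = 0.806). In simulated arrays with independent genes the estimated correlation let a list shift of 0.3 log2 be found in 0 of 10 draws of this comparison, of 0.5 in 7 and of 0.8 in 10. The correlations estimated here were 0.39 for the sterol and 0.89 for the neutrophil list. Draws with independent genes therefore cannot tell whether the number of arrays is why larger shifts were lost. The neutrophil genes were high in 1 KO array, with a list mean of 8.89 in unstimulated KO array 2 against 6.24 to 7.44 in the 6 Rag experiment arrays that were not KO arrays 2. Without KO array 2 the number of genes called was 530 (69 higher, 461 lower, all 22 among them). It was 1 without WT array 1, 0 without WT array 2, 9 without either stimulated KO array and 5 without either stimulated WT array. None of 13 named genes, Rraga included, was called whichever array was left out.

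In stimulated Tregs most genes called for loss of Rag were higher, each called gene having changed at least 2-fold. Plac8 rose by 3.27 ± 0.37 log2 (SE, n = 2 arrays per group; adjusted p = 0.00445), Eps8l1 by 3.05 ± 0.26 (adjusted p = 0.000238) and Hpgds by 3.00 ± 0.41. Il4 (2.81 ± 0.47, adjusted p = 0.0426), the iron reductase gene Cybrd1 (2.55 ± 0.22, adjusted p = 0.000238) and Ermn (2.11 ± 0.29) rose too. Nt5e fell (-1.56 ± 0.24, adjusted p = 0.0287). Besides Rraga it was the 1 other gene called lower, of 20 called in all (18 higher, 2 lower), and 988 genes had an unadjusted p under 0.05. A second quantile normalization called 42 (39 higher, 3 lower). Eps8l1 and Ermn rose from WT levels below the 25th percentile of each array compared, so the sizes of their rises are uncertain. Il2ra, Ctla4, Myc and Mki67 were not called (0.74, -0.53, 0.22 and 0.13).

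Interferon-induced genes were higher, 30 of 36 above 0, with Usp18 called (1.93 ± 0.31) and 9 higher when adjusted over the list alone (median 0.54, adjusted p = 2.4e-15). Lysosomal and autophagy genes were higher, 31 of 41 above 0, none called and 9 when adjusted over the list alone (median 0.47, adjusted p = 2.9e-11). The same list had a median of -0.10 in stimulated Rheb KO. Ribosome biogenesis genes were lower, 40 of 42 below 0 with none called by either adjustment (median -0.43, adjusted p = 1.5e-09). Of ribosomal protein genes, 31 of 32 lay above 0, none called by either adjustment (median 0.24, adjusted p = 0.00014; 0.0349 and not called after a second quantile normalization). Nucleotide and one-carbon genes shifted by -0.42 with none of 25 called by either adjustment (adjusted p = 6e-05; -0.22 and not called without KO array 1). Of 24 cytokine genes Il4 rose, and 4 rose and 1 fell when adjusted over the list alone (median 0.31, adjusted p = 0.00057). Of 35 T cell receptor genes none was called and 4 rose when adjusted over the list alone (median 0.22, adjusted p = 0.00057). Neutrophil genes were again higher, with none of 10 called by either adjustment (median 0.69, adjusted p = 0.0017). Without KO array 2, whose list mean was 8.63, their median was -0.10. Dendritic genes were called higher although 6 of 12 lay below 0, with none called and 2 higher when adjusted over the list alone (median -0.00567, mean 0.30, adjusted p = 0.0423). Their list was not called without KO array 2 (median -0.10) or WT array 1 (-0.0275). Of 40 lists 18 were called, and none held with an estimated correlation (adjusted p = 0.833 with an estimated correlation for each list named). The fry test called none either (smallest adjusted p = 0.866). Without either unstimulated KO array 109 genes were called, all 20 among them, and without either unstimulated WT array 5 were. Without stimulated KO arrays 1 and 2 and WT array 2 the numbers were 2, 6 and 3. Eps8l1 and Cybrd1, 2 of 9 named genes called, were called whichever array was left out.

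**Figure D3:**
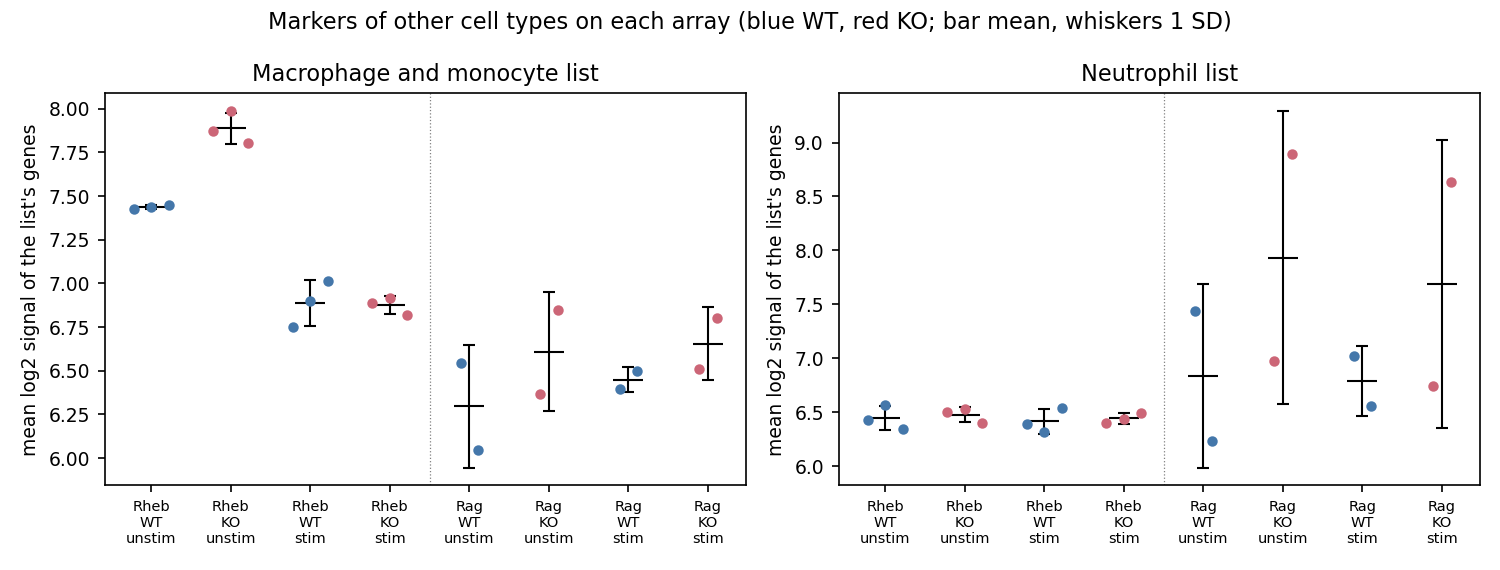
Mean log2 signal of the macrophage and neutrophil marker lists in each array, by group. The neutrophil mean was 8.89 and 8.63 in the Rag KO arrays numbered 2 and at most 7.44 in the other Rag experiment arrays, and the macrophage mean was 7.80 to 7.99 in unstimulated Rheb KO against 7.43 to 7.45 in unstimulated WT.

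After stimulation for 8 h in the Rag experiment, 8 of 35 T cell receptor-induced genes were higher in WT and 12 in KO. Their list held neither with an estimated correlation nor by fry. The sources used here do not name the stimulus, so its effect cannot be told apart from one of the time itself. In WT Tregs the cell cycle inhibitor gene Cdkn1a rose by 3.53 ± 0.31 log2 (SE, n = 2 arrays per group; adjusted p = 0.000558). The transcription factor genes Irf4 (2.70 ± 0.30), Fosl2 (2.54 ± 0.30), Tbx21 (2.48 ± 0.43) and Nr4a3 (2.46 ± 0.30) followed. Ifit1bl1 (-3.09 ± 0.29), Ifi213 (-2.52 ± 0.25), Dtx1 (-2.50 ± 0.39), Fos (-2.49 ± 0.28) and Sit1 (-2.47 ± 0.29) fell most. In Rag KO, Ramp3 (3.52 ± 0.46), Il4 (3.44 ± 0.47), Nfil3 (3.38 ± 0.41), Cdkn1a (3.27 ± 0.31), Zdhhc23 (3.05 ± 0.43) and Iigp1 (3.01 ± 0.34) rose most. Dtx1 (-3.12 ± 0.39), Ccr9 (-2.57 ± 0.32), Cd7 (-2.12 ± 0.32) and Sit1 (-2.12 ± 0.29) fell most. Il2ra rose in KO (1.43 ± 0.24, adjusted p = 0.0109) and was not called in WT (0.81 ± 0.24, adjusted p = 0.144), with a difference that was not called (adjusted p = 0.728). In WT 195 genes were called (93 higher, 102 lower) and in KO 258 (234 higher, 24 lower), 64 of them in both and none in opposite ways. At an unadjusted p under 0.05 there were 2932 and 2800 genes. The median change of all genes was 0.21 in WT and 0.04 after a second quantile normalization, which called 638 genes in WT (208 higher, 430 lower) and 382 in KO (215 higher, 167 lower).

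Of the T cell receptor-induced genes 21 rose in WT and 24 in KO when adjusted over the list alone (median 0.80 and 1.17, adjusted p = 6.7e-14 and 1.2e-19). Of 42 ribosome biogenesis genes 5 rose in WT, among them Nop16 (1.55 ± 0.28) and Nolc1 (1.54 ± 0.26), and none in KO. With p adjusted over the list alone, 34 and 26 rose (median 0.92 and 0.72, adjusted p = 3.3e-18 and 7e-13). Of 24 resting genes 5 fell in WT, led by Pik3ip1 (-1.93 ± 0.30), Nsg2 (-1.54) and S1pr1 (-1.52), and Id3 fell in KO (-2.12 ± 0.34). When adjusted over the list alone 11 and 4 fell (median -0.64 and -0.18, adjusted p = 1.9e-20 and 0.00046). Of 24 cytokine genes 4 rose in WT and 7 in KO, where Ifng rose by 2.78 ± 0.39. Adjusted over the list alone, 10 and 12 rose (median 0.52 and 0.67, adjusted p = 0.00096 and 8.8e-07; in WT 0.62 and not called without stimulated WT array 1). Of 33 effector Treg genes 7 rose in KO, with Tigit (2.51 ± 0.29) and Ccr8 (2.26 ± 0.33) beside Nfil3 and Irf4, and 12 rose when adjusted over the list alone (median 0.85, adjusted p = 1.4e-07). Interferon genes shifted lower in WT, where Cmpk2 (-2.03), Herc6 and Isg15 fell and Gbp2 rose (9 falling and 3 rising when adjusted over the list alone; median -0.20, adjusted p = 3.7e-08). They shifted higher in KO, where Gbp2 (2.68), Igtp (2.33), Irgm1 (1.90) and Usp18 (1.76) rose (9 rising and 1 falling when adjusted over the list alone; median 0.35, adjusted p = 0.0366). In KO their list was not called without unstimulated KO array 2 (0.32) or stimulated KO array 1 (0.35), or after a second quantile normalization (0.0468). Cmpk2 averaged 5.96 in stimulated WT, below the negative control median of each WT array, so the size of its fall is uncertain. None of these lists held with an estimated correlation (adjusted p = 0.909 in WT, 0.655 in KO and 0.743 for the interferon list in KO, with an estimated correlation). Simulated list shifts of 0.8 log2 were found in 10 of 10 draws in each genotype, but with independent genes, so these draws cannot tell why the lists were lost. By fry no list was called in WT or KO (smallest adjusted p = 0.281 and 0.258). In WT the number of genes called was 600 without either unstimulated KO array, 13 without unstimulated WT array 2, and 51 and 23 without stimulated WT arrays 1 and 2. In KO it was 132 (94 higher, 38 lower) and 1948 (1853 higher, 95 lower) without unstimulated KO arrays 1 and 2, and 45 without either stimulated KO array. Cdkn1a, Irf4, Ifit1bl1, Ifi213, Fos and Sit1, 6 of 42 named genes called in WT, were called whichever array was left out. In KO 17 of 46 were, including Ramp3, Il4, Nfil3, Cdkn1a, Tigit and Ifng.

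For the interaction of Rag loss and stimulation limma called no gene, 1202 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.728. The response of the interferon list lay higher in KO than in WT by camera (31 of 36 above 0, none called and 14 higher when adjusted over the list alone; median 0.76, adjusted p = 4e-12; adjusted p = 0.918 with an estimated correlation). The core Treg list (16 of 17 above 0; median 0.63, adjusted p = 3.1e-05) and the resting list (22 of 24 above 0; median 0.65, adjusted p = 8.8e-07) had none called by either adjustment and were lost likewise (adjusted p = 0.918 with an estimated correlation for each). No list was called by fry (smallest adjusted p = 0.991). Without unstimulated KO array 2 the interaction called 387 genes (361 higher, 26 lower), and without stimulated WT array 1 it called 1. Across genes the responses of WT and KO correlated with r = 0.34.

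The last comparison asked where losing Rag differs from losing Rheb, each measured against its own WT arrays. Its 1 fit shares 1 spread per gene between the experiments, whose median SE of a knockout effect was 0.26 (Rag) and 0.13 (Rheb). For Nt5e in stimulated Tregs the SE of the difference (0.21) lay below that of the Rag effect alone (0.24). The SEs and adjusted p of the differences may therefore be too small. In unstimulated Tregs the effects on Hpgds (difference 3.10 ± 0.43 log2, SE, adjusted p = 0.00247), Il4 (2.72 ± 0.48, adjusted p = 0.0365), Ccr9 (2.42 ± 0.45), Eps8l1 (2.41 ± 0.42), Lilr4b (2.31 ± 0.33) and Col27a1 (2.17 ± 0.31) were more positive for Rag. Those on Rraga (-2.51 ± 0.25), Elovl5 (-1.50 ± 0.27) and Trat1 (-1.49 ± 0.27) were more negative. Eps8l1 averaged 8.19 in unstimulated Rag KO and 5.62 in Rag WT, against 8.28 in Rheb KO and 8.11 in Rheb WT. Its difference therefore rests on a Rag WT level far below the 3 other groups. Why the WT levels of the experiments differ was not tested. Il4 fell by 1.31 in Rheb KO and was not called in Rag KO (1.40, adjusted p = 0.608). Differences were called for 11 genes (8 higher, 3 lower in Rag KO), 7 of them with effects of opposite sign, and 1426 had an unadjusted p under 0.05. A second quantile normalization called 21 (13 higher, 8 lower). In stimulated Tregs Il4 (3.30 ± 0.48, adjusted p = 0.00217), the transporter gene Abcb1a (2.98 ± 0.41), Hpgds (2.90 ± 0.43) and Plac8 (2.87 ± 0.44) were more positive for Rag. So were Pdzk1ip1 (2.56 ± 0.51), Cybrd1 (2.44 ± 0.30), Usp18 (2.12 ± 0.31), the lysosomal hexosaminidase gene Hexa (1.94 ± 0.33) and Rhebl1 (1.54 ± 0.29). Rhebl1 is itself targeted in the Rheb KO, and its levels there (5.94 in WT, 5.18 in KO) lay below the 25th percentile of the arrays. Rraga (-2.06 ± 0.25), Ccr6 (-1.55 ± 0.31) and Nt5e (-1.23 ± 0.21) were more negative. Differences were called for 37 genes (34 higher, 3 lower), 26 of them with effects of opposite sign, and 1377 had an unadjusted p under 0.05. Here a second quantile normalization called 64 (61 higher, 3 lower). Choosing genes by a large difference favours effects of opposite sign, and of the 37 genes 15 were called in Rag KO and 6 in Rheb KO. The counts of opposite sign in either state therefore do not show that the knockouts act in opposite ways. Lysosomal genes differed after stimulation (34 of 41 above 0, Hexa called and 14 higher when adjusted over the list alone; median 0.54, adjusted p = 4.6e-14). So did interferon genes (28 of 36 above 0, Usp18 called and 7 higher when adjusted over the list alone; median 0.37, adjusted p = 1.5e-08). Mitosis genes shifted by 0.32 (none of 38 called by either adjustment, adjusted p = 0.00087), and by 0.0496, not called, without stimulated Rag WT array 2. These 3 lists had an adjusted p = 0.938 with an estimated correlation, and fry called no list in either state (smallest adjusted p = 0.516 and 0.628). Without 1 array the unstimulated count was 6 (Rheb WT array 3), 5, 6 and 6 (Rheb KO arrays 1, 2 and 3), 165 and 7 (Rag WT arrays 1 and 2) or 871 (Rag KO array 2). The stimulated count was 15 (Rag KO array 1), 130 or 12 (Rag WT arrays 1 and 2). Rraga, Hpgds, Lilr4b and Col27a1 unstimulated, and Rraga, Il4, Abcb1a, Hpgds, Cybrd1 and Usp18 stimulated, were called whichever array was left out.

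Some genes moved the same way in both knockouts. In unstimulated Tregs 6 genes were called in both, Itga9 higher and Nt5e, Prg4, Dapl1, Ddx43 and H2-Ob lower (the last 2 named after their values were seen). Of the 99 genes called in Rheb KO, 82 (82.8%) had the same sign in Rag KO, against 60.1% of all genes. In stimulated Tregs Ermn was called in both, and 83 of 106 (78.3%) had the same sign, against 52.97% of all genes. Across genes, which are not independent replicates, the knockout effects correlated with r = 0.28 (Spearman rho 0.26) in unstimulated and r = 0.16 (rho 0.09) in stimulated Tregs. The latter was 0.0594 without stimulated Rheb WT array 3, 0.08 without stimulated Rag WT array 1 and 0.25 without stimulated Rag WT array 2. The responses to stimulation correlated between the experiments with r = 0.49 in WT and 0.53 in KO, with 129 and 173 genes called in both. Genes induced by stimulation in WT arrays of the Rheb experiment (200 genes) were higher in stimulated Rag KO by a mean of 0.29 log2 (SD over genes 0.60, camera p = 7e-12; p = 0.248 with an estimated correlation). The 200 reduced genes were higher by 0.27 (SD 0.60, camera p = 3.2e-10; p = 0.323 with an estimated correlation). These means were 0.52 and 0.42 without stimulated Rag WT array 1 and 0.07 and 0.12 without stimulated Rag WT array 2. Genes induced in WT arrays of the Rag experiment (93 genes) did not shift in stimulated Rheb KO detectably (mean -0.00, SD over genes 0.35). They passed camera's threshold in opposite directions without stimulated Rag WT array 2, which left 13 such genes (0.11), and without the Rag KO arrays numbered 2 (-0.0635). The 102 reduced genes shifted by -0.07 (camera p = 0.0495; p = 0.243 with an estimated correlation), which turned to 0.03 and 0.09 without stimulated Rag WT arrays 1 and 2.

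**Figure D4:**
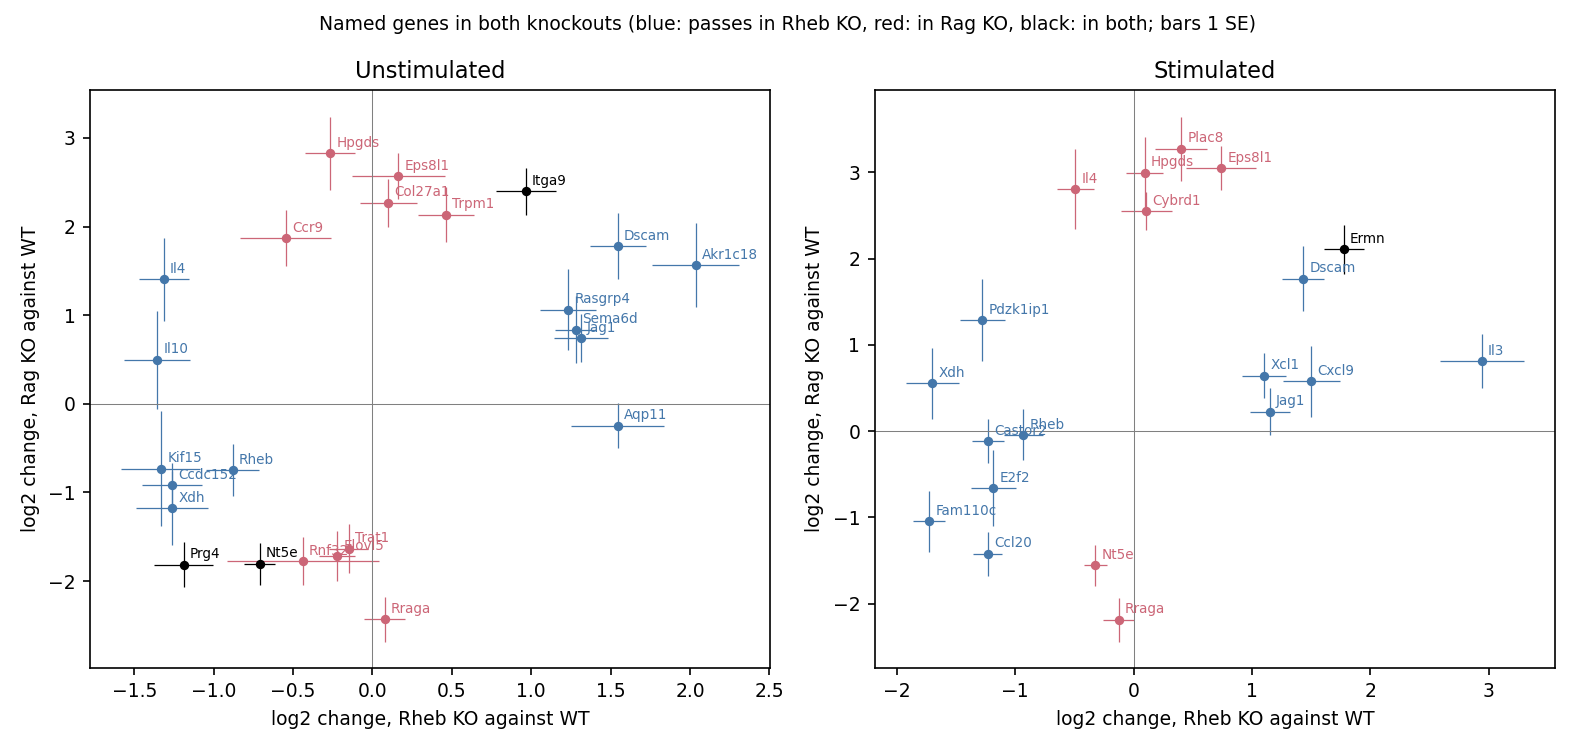
Log2 change of the named genes in Rheb KO (x axis) and Rag KO (y axis), unstimulated and stimulated, with bars of 1 SE and colours for genes called in the Rheb KO (blue), the Rag KO (red) or both (black). Nt5e and Prg4 lie lower in both knockouts of unstimulated Tregs, at -0.71 and -1.80 for Nt5e, and Il4 lies at -0.49 in stimulated Rheb KO and 2.81 in stimulated Rag KO.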

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

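Tests chosen after the result was seen are those of induction by loss of Rag, of a lower share of sorted cells, the 3 for the direction of the calls in the Rag KO response to stimulation, and the count of granulocyte genes higher in both KO arrays 2.

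The differences between the Rag and Rheb knockout effects passed limma's test for 11 genes in unstimulated and 37 genes in stimulated Tregs. In unstimulated Tregs the named genes were Hpgds (3.10 log2, Rag effect minus Rheb effect), Il4 (2.72), Ccr9 (2.42), Eps8l1 (2.41), Lilr4b (2.31), Col27a1 (2.17), Trat1 (-1.49), Elovl5 (-1.50) and the targeted Rraga (-2.51). In stimulated Tregs they were Il4 (3.30), Abcb1a (2.98), Hpgds (2.90), Plac8 (2.87), Pdzk1ip1 (2.56), Cybrd1 (2.44), Usp18 (2.12), Hexa (1.94), Rhebl1 (1.54, targeted in the Rheb KO), Nt5e (-1.23), Ccr6 (-1.55) and Rraga (-2.06). Of the unstimulated genes 8 were called in the Rag KO and 1 in the Rheb KO, and of the stimulated genes 15 and 6. Genotype effects were each taken within 1 experiment, but the experiments also differ in array number, signal level and perhaps in the time of stimulation, and such differences remain among the open explanations beside the GTPase lost. The fit also shares 1 spread per gene between experiments of unlike spread, so these counts may be too high. For Eps8l1 the unstimulated WT levels were 5.62 in the Rag and 8.11 in the Rheb experiment, with KO levels of 8.19 and 8.28. Without Rag KO array 2 the unstimulated count was 871 and without Rag WT array 1 the stimulated count was 130.

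Neutrophil genes were high in the Rag KO arrays numbered 2 of both states, with list means of 8.89 and 8.63 against 6.24 to 7.44 in the 6 remaining Rag experiment arrays. An array-wide difference in signal is argued against by quantile normalization, after which the smaller median difference between arrays 2 and 1 was still 1.65. Induction by loss of Rag to a like size in every KO array is argued against. KO arrays 1 differed from the WT mean by a median of -0.10 in the stimulated and 0.23 in the unstimulated state. KO arrays 2 exceeded KO arrays 1 by a median of 1.77 and 2.05 in these states. The list means of the WT arrays themselves were 6.56 and 7.02, and 6.24 and 7.44. Induction in only some KO samples stays open. RNA of granulocytes, which CD4 bead enrichment and the CD25+CD4+ sort would remove, stays open, with Mpo (10.6 and 9.78), Ngp (10.4 and 9.41) and Camp (9.84 and 9.12) among the most abundant genes of a list of 10, of which 0 are in another list and 1 exceeds the median of every unstimulated WT array of the experiment. A second set of 21 granulocyte genes differed by a median of only 0.38, below the bound of 0.5 set beforehand against this explanation. That bound was judged wrong after the result was seen, because 18 of the 21 lie below the lowest array median (7.18) in the 6 other arrays, and because 9 of the 21 (42.9%) were higher in both KO arrays 2 than in all 6 others, against 355 of 19474 other genes (1.82%).

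Macrophage genes, and with them dendritic cell genes, were higher in the unstimulated Rheb KO arrays, at macrophage list means of 7.80 to 7.99 against 7.43 to 7.45 in WT. Array-wide signal is argued against by quantile normalization (camera, adjusted p = 1.7e-07 for the list). A lower share of sorted cells that raised every other cell type alike is argued against by the CD8 T cell list. The macrophage list rose above it by 0.43 ± 0.10 (SE), and above the B cell and platelet lists by 0.32 ± 0.10 and 0.39 ± 0.0616. These gaps do not test a lower share of sorted cells through only some cell types. Of the CD8 T cell, B cell and platelet genes, 3 of 7, 2 of 12 and 5 of 6 exceeded the median of every unstimulated WT array. The NK list rose with the macrophage list (0.33 ± 0.0852, a gap of 0.12 ± 0.0654) and also after stimulation (0.24 ± 0.0852), where the macrophage list did not (-0.0138 ± 0.0694), so that a larger share of several cell types stays open. RNA of macrophages carried through the CD4 bead enrichment and CD25+CD4+ sort is a candidate source, since a second set of 24 macrophage genes, written before it was examined, rose by a median of 0.46 with 22 above 0. The abundant C1qa reached 8.66 to 8.82 in KO against 7.32 to 7.88 in WT, and of the 12 list genes 1 is in another list and 3 exceed the median of every unstimulated WT array of the experiment. Higher expression by the KO Tregs themselves was not tested and stays open.

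The response to stimulation in Rag KO was called mostly higher, 90.7% of calls against 47.7% in WT. Array-wide signal may account for part of it, since 56.3% were higher after quantile normalization (32.6% in WT), and so may the unstimulated KO array of lowest signal, without which 71.2% were higher (95.1% without the other unstimulated KO array). Quantile normalization changed mainly the number of lower calls, from 234 higher and 24 lower to 215 higher and 167 lower. These totals do not show whether the same genes stayed called. A response that differs between the genotypes was not shown, with 0 genes called for the interaction by limma and 1202 at an unadjusted p under 0.05. The interaction called 387 genes (361 higher, 26 lower) without unstimulated KO array 2 and 196 without both KO arrays 2. The count of 0 cannot tell, since simulated 2-fold interactions were recovered for 6.87% of genes.

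Other splits of the 6 arrays of a Rheb experiment comparison number 10 with the real 1, too few for a share under 0.05. The real splits called 99, 106, 1828 and 1901 genes, and the highest of the other splits called 1, 0, 1 and 0. For the interaction 0 genes were called, so all 100 splits drawn call at least as many whatever the arrays hold, and this count says nothing about chance; the highest other called 268. That split exchanges the genotypes in 1 state, which makes it the knockout effect over both states, and so points to a structure of the samples.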

How the results depend on the processing

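The alternatives that leave out Rag KO arrays 2, the 2 arrays of lowest signal, or genes that follow macrophage genes were chosen after seeing the data.

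Counts of called genes were not stable, and some named-gene calls lost the threshold. Of 410 calls of named genes, 399 kept direction and threshold after a second quantile normalization, 401 with a trended and robust prior and 373 with the replicate number as a block, and none reversed. Of 4438 such calls over the arrays left out in turn, 3607 kept both and 831 lost the threshold. The prior and the replicate block leave the log2 change as it was, so neither can reverse a direction. Leaving out an array cannot reverse a call whose arrays did not overlap between the groups. No called knockout effect within an experiment, and no called response in the Rag experiment, had such overlap. The lack of reversals in these settings therefore does not show that directions were stable. A reversal was possible after quantile normalization, and none occurred. Of 194 list calls 17 kept the threshold with an estimated correlation, all in the Rheb experiment, 143 after quantile normalization and 191 with the block; the cell cycle and sterol lists in both Rheb KO comparisons kept it in all 3.

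The cause was not tested for the following changes, except that fewer arrays or fewer genes entered a fit where arrays or genes were left out. The trended and robust prior called 200 genes for Rheb KO unstimulated, 214 for Rheb KO stimulated and 7 for the Rheb interaction; in the Rag experiment it called 96 and 106 for KO unstimulated and stimulated, 490 and 553 for stimulation of WT and KO and 10 for the interaction, and 6 for the unstimulated difference between knockouts. One fit of all 20 arrays called 28, 13, 806, 920 and 1 genes for the 5 Rheb comparisons in the same order and 210, 227, 1930, 2146 and 25 for the Rag comparisons. That fit shares 1 spread per gene between the experiments. Only the 2 groups compared gave 27 and 59 for Rheb KO and 1170 for stimulation of Rheb WT, and 12, 274, 649 and 60 for the first 4 Rag comparisons. Without dim genes the interactions of Rheb and of Rag called 1 gene each, the first 4 Rag comparisons 36, 57, 354 and 529, and the unstimulated difference 17. The replicate block called 52 genes for stimulated Rheb KO and 42 for stimulated Rag KO; in the Rheb experiment residuals of equal replicate numbers correlated across genes with r from -0.18 to 0.18, within the range of unequal numbers (-0.19 to 0.26). In the Rag experiment, where 2 arrays per group make r of unequal numbers the negative of that of equal numbers, equal numbers gave -0.0220 and 0.0980 for KO against WT and 0.23 and 0.17 for stimulated against unstimulated arrays, which leaves open whether the numbers mark a shared origin there. Quantile normalization called 43, 42 and 638 genes for Rag KO unstimulated, stimulated and stimulation of Rag WT, and 21 and 64 for the differences, and moved the correlation of unstimulated knockout effects to 0.22. Without Rag KO arrays 2 the 5 Rag comparisons called 486, 93, 649, 669 and 196 genes and the differences 820 and 59, and genes induced in Rag WT shifted by -0.0635 in Rheb KO, past the threshold. Leaving out 2637 genes that follow macrophage genes within groups, or are in a list of such cells, left 82 of 99 calls of unstimulated Rheb KO, which counts the called genes among them and tests no cause. Without the 2 arrays of lowest signal 274 genes were called for stimulated Rag KO, 565 for stimulation of Rag WT, and 3 and 124 for the differences.

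Leaving out each array in turn gave 39 to 104 and 25 to 106 genes for Rheb KO unstimulated and stimulated, 1263 to 1802 and 1356 to 2011 for stimulation of Rheb WT and KO, and 0 for the interaction; 0 to 530 and 2 to 109 for Rag KO, 13 to 600 and 45 to 1948 for stimulation of Rag WT and KO, and 0 to 387 for the interaction; and 5 to 871 and 12 to 130 for the differences. Correlations of knockout effects ranged from 0.19 to 0.36 unstimulated and from 0.0594 to 0.25 stimulated. Mean shifts of responsive genes ranged from 0.07 to 0.52 and from 0.12 to 0.42 in Rag KO, from -0.0485 to 0.11 for genes induced in Rag WT (0.11, past the threshold, without stimulated Rag WT array 2), and from -0.0864 to 0.0911 for genes reduced in Rag WT, which reversed to 0.0340 and 0.0911 without stimulated Rag WT arrays 1 and 2. Some lists reversed. Ribosomal proteins changed from -0.25 to 0.0423 (Rag KO unstimulated) and from 0.14 to -0.0529 (stimulated difference) after quantile normalization. The first was also 0.13 without unstimulated Rag WT array 1, -0.0347 without KO array 1, -0.57 without WT array 2 and -0.46 without KO array 2; the second was 0.12 without stimulated Rheb WT array 1, and 0.0517 and 0.0548 without stimulated Rag WT and KO arrays 2, not called in each, and 0.25 and 0.26 without Rag KO and WT arrays 1. Neutrophil genes changed to -0.105 (Rag KO stimulated) and -0.255 (stimulated difference) without stimulated Rag KO array 2 or without both KO arrays 2, and to 1.95 and 1.99 without stimulated Rag KO array 1. Effector Treg genes changed to -0.0937 (Rag KO stimulated) and -0.0401 (stimulated difference) without stimulated Rag WT array 2, and to 0.56 and 0.58 without stimulated Rag WT array 1. Mitochondrial biogenesis genes (stimulated difference) ranged from -0.35 to -0.0280, the latter without stimulated Rag KO array 1, where the direction of the set test reversed. Where an array left out leaves 1 in its group, that array is assumed to vary like the other groups. The median SE of a knockout effect was 0.13 log2 in the Rheb and 0.26 in the Rag experiment, and between 2194 and 3548 genes per array exceeded the 95th percentile of negative controls, which limits what dim genes can show.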

Other observations

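The test over both states and the genes named from it were chosen after the results above were seen, while the tests of the second lysosomal set and of neighbouring genes were set before their results were seen. The test over both states counts unstimulated and stimulated arrays as separate samples, and the labels do not say whether they share animals. If they do, its calls may be too many. In the Rag experiment residuals of equal replicate numbers correlated between states with r = 0.23 in WT and 0.17 in KO.

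Averaged over both states, loss of Rheb was called for 268 genes (87 higher, 181 lower), 131 of them in neither state alone. Those called in neither state alone included the DNA glycosylase gene Neil3 (-0.92 log2, adjusted p = 0.0591 after quantile normalization), the centriole gene Stil (-0.87), the cell cycle genes E2f8 (-0.86) and Top2a (-0.57), the sterol genes Hsd17b7 (-0.83) and Stard4 (-0.58), the adhesion gene Selp (-1.19 ± 0.26, SE, adjusted p = 0.0447) and the integrin gene Itgb8 (-0.61, adjusted p = 0.00989). Higher were Nrp2 (0.74, adjusted p = 0.00933), Icosl (0.86), the myeloid transcription factor gene Spi1 (0.72), and the transcription factor genes Rora (0.54, adjusted p = 0.0047) and Ahr (0.43, adjusted p = 0.0121). Marker genes of myeloid, NK and dendritic cells rose beside them, with Fcgr3 (0.66), Fcer1g (0.47) and H2-Eb1 (0.80) called and list medians of 0.16 (macrophage), 0.29 (NK) and 0.25 (dendritic), so the rises of Spi1 and Icosl are not shown to be those of Tregs. Of 38 G1/S genes 5 fell (median -0.23, adjusted p = 0.00475 with an estimated correlation), of 38 mitosis genes 8 (median -0.28, adjusted p = 0.0094 with an estimated correlation) and of 20 sterol genes 6 (median -0.38, adjusted p = 0.00475 with an estimated correlation). Leaving out each array in turn gave 179 to 290 genes, and quantile normalization 266, of which 234 were shared.

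Averaged over both states, loss of Rag was called for 64 genes (47 higher, 17 lower), 32 of them in neither state alone. They included the inhibitory receptor gene Lilrb4a (2.35), the antigen presentation genes H2-DMb2 (1.78) and H2-Aa (1.44), the lysosomal glucosidase gene Gaa (1.45), Bhlhe40 (1.33) and, lower, Nod1 (-1.08). Akr1c18 (2.10) and Dscam (1.77, adjusted p = 0.0107) rose here and in the Rheb KO (1.61 and 1.49), and Bmp7 (-1.54), Npas4 (-1.25) and Gsta4 (-0.90) fell here and in the Rheb KO (-0.93, -1.08 and -0.89). H2-Aa and Ccr9 (1.24) belong to the dendritic list, and the list medians were 0.16 (dendritic), 1.04 (neutrophil), 0.33 (NK) and 0.10 (macrophage), so the rises of Lilrb4a and the antigen presentation genes are not shown to be those of Tregs. Leaving out each array in turn gave 9 to 162 genes, and quantile normalization 138, among them all 64.

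The rise of lysosomal genes in stimulated Rag KO was tested as a hypothesis of a wider rise, on a second set of 37 lysosomal genes. Their median change was 0.37 with 30 above 0 (camera p = 1.5e-11; p = 0.161 with an estimated correlation), 0.32 after quantile normalization and between 0.25 and 0.54 with 1 stimulated array left out, against -0.09 in stimulated Rheb KO.

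Among the 200 measured genes nearest to Rheb and Rhebl1, 0 were called by limma in the Rheb KO, where 1.80 would be expected from 176 called anywhere. Carried-along neighbours among these 200 genes therefore account for none of the calls, while genes farther from the targeted genes were not tested. Among the 200 nearest to Rraga and Rragb, 1 was called in the Rag KO, Col27a1, where 0.349 would be expected, which is too few to decide.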
